A study of Mus musculus with 3 samples.

How the data were processed

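Hepatocyte RNA of 3 groups of mice was measured on 3 arrays of 1 colour (Cy3), 1 array per group. The spot intensities were made by the scanner software Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, which subtracted the background and detrended each array, per the file headers. The deposited value table holds a linear ratio for 23206 spots. Comparison with the scanner files showed that each value is the processed signal divided by that array's 75th percentile over non-control spots, with a largest relative deviation of 2e-08, and that the rows are the spots well above background and not marked non-uniform on all 3 arrays. Its column medians are 0.79, 0.80 and 0.81, and its scale and centring are thereby known. Each column was matched to a sample, and 0 columns were left unmatched. Spot classes and flags, such as well above background, are other values set by the scanner software, per the file headers. Probe positions are those in the files, on build mm9.

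The main values were log2 of the processed signal minus the log2 of the array's 75th percentile over 43020 non-control spots, which was 574 for standard diet, 500.3 for HFD-IgG and 514 for anti-VLA-4. Spots marked as non-uniform or population outliers were left out and spots of a probe averaged. Of 39429 probes, 26055 (66.1%) were named through their accession in a RefSeq table, and the others kept the array's own gene name, which can be old. Each of 31870 symbols took its probe with the highest mean over the arrays, and 6278 symbols had more than 1 probe. Probes of a gene differed by at least 2-fold in opposite directions for 38 of 4157 genes with several probes in HFD-IgG over standard diet, 41 of 4281 in anti-VLA-4 over HFD-IgG and 18 of 3941 in anti-VLA-4 over standard diet. A gene was compared when well above background on at least 1 of the arrays. Where the dimmer array was not well above background, the fold is a lower bound against the higher of the probe's own signal and the lowest signal well above background, and is written as at least that fold or no less than it.

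With 1 array per group there is no test. Genes at least 2-fold different were counted. The median of each list fixed before the data were examined, with at least 5 measured members, was set against 10000 random lists of the same size matched on mean signal in 20 bins. Genes named in the text were set by a rule, for each comparison: the 8 highest and 8 lowest measured on both arrays with every probe the same way by at least 1.5-fold, leaving out clones and predicted loci; up to 4 members of each list that stood apart; up to 2 members of other lists at least 2-fold different; and Itga4, Itgb1 and Vcam1. The text names part of them, and some genes that the rule took are not reported here. Genes of families with near-identical members are uncertain between copies. Receptor probes and spots of control probes were examined in addition.

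The steps were tested on simulated arrays made from the standard-diet array with scanner error, for HFD-IgG over standard diet over 18186 genes. Of 50 genes changed by each size, 50 were called at 8-fold, 50 at 4-fold, 44 at 2.5-fold and 1 at 1.5-fold, and 17 of 17986 unchanged genes were called. Of 200 unchanged lists, drawn at random from the unchanged genes, 10 stood apart. Every simulated array kept the flags of the standard-diet array, and dim spots got no error. Calls against an array where a probe was not well above background could therefore not arise. The simulation checks the steps and gives no rate of false calls for the measured arrays.

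Alternatives were quantile scaling, the median of bright probes, cyclic loess, normexp background correction with offset 50 fitted on all spots, other filters on dim genes, the mean over probes, other thresholds and the deposited value table. Others were chosen after seeing the data: probes of at most 50% purines, genes above the 75th percentile, random lists matched on purines, and the mirrored share. No replicate could be left out. The standard-diet and HFD-IgG arrays shared a slide, and the anti-VLA-4 array lay on another. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.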

Results

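Gene expression was measured in hepatocytes isolated with collagenase from fasted male C57BL/6 mice on 3 single-colour arrays, with 1 array per group. The first array held RNA of mice on a standard diet (the standard-diet array, SD). The second held RNA of mice on a high-fat diet given control IgG (the HFD-IgG array), and the third RNA of mice on a high-fat diet given an antibody that blocks VLA-4 (the anti-VLA-4 array). VLA-4 is an integrin of leukocytes, made of the chains encoded by Itga4 and Itgb1, and Vcam1 encodes its ligand on endothelial cells. Mice entered the diet at 6 weeks of age and stayed on it for 16 weeks, and antibody or IgG was injected 2 times a week over the last 6 weeks. The labels do not say how many mice contributed to an array.

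Of 43020 non-control spots, 57.3% were well above background on the standard-diet array, 66.5% on the HFD-IgG array and 62.4% on the anti-VLA-4 array, and 0 were saturated. The median SD of log2 signal over repeated spots of a probe was 0.08, 0.10 and 0.08 on these arrays, and the scanner's own error of a bright spot was about 10.1% of its signal. This is error within an array. With normexp background correction most differences of the genes chosen by rule to be named moved by more than the scanner error, 255 against 57 that did not and 2 that reversed. No group has a replicate array, so no difference below has a replicate check, no p-value is given, and the spread between mice, preparations and hybridisations is unknown. The number of arrays limits the precision. Genes are described by a fixed rule of size, at least 2-fold, and gene lists by the percentile of their median among 10000 random lists of like signal, which describes these arrays and is not a p-value. A list is said to stand apart when its median lay in the lowest or highest 2.5% of those lists. Lists of unrelated genes would give 1.70 to 1.75 such lists in a comparison. The fixed lists share members, and their genes can vary together between mice or preparations. More of them could therefore stand apart without an effect of diet or antibody, and their number is not evidence of one.

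The first comparison, HFD-IgG over standard diet, asks how expression in the hepatocyte preparations differed on the high-fat diet. The labels list injections of IgG for the high-fat diet mice and none for the standard-diet mice, so diet and injection differed together. The medians of the lists of Kupffer, sinusoidal endothelial and stellate cell markers, interferon-stimulated genes, MHC class II and cytokines stood above random lists on the HFD-IgG array, while those of fatty acid oxidation and male-biased liver genes stood below them. Cidea, which encodes a lipid droplet protein, was 42.2-fold higher (log2 difference 5.40, scanner error 0.23; chromosome 18, 67527351 to 67527410, build mm9). Cfd, encoding complement factor D, was 23.4-fold higher. Igfbp1, an insulin-suppressed gene of the liver (chromosome 11, 7102442 to 7102501), was 8.37-fold lower.

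Of 28 measured acute phase genes, 7 were at least 2-fold higher, 0 were 2-fold lower and 21 lay between, with a list median of 0.35 in log2 that stood apart. With normexp background correction that median was -0.28, still above the random lists. Saa1 was 19.4-fold and Saa2 21.1-fold higher, although these near-identical copies cannot be separated with certainty, and Lcn2 was 15.1-fold higher. Of 33 interferon-stimulated genes, 20 were at least 2-fold higher and 0 lower (median 1.21), among them Oas1a at 11.5-fold and Gbp3 at 6.37-fold. Of 10 genes of MHC class II presentation, 8 were higher (median 2.88), with H2-Ab1 at 7.99-fold and H2-Eb1 at 8.47-fold, both members of a family of similar genes. Of 24 cytokine and chemokine genes, 18 were higher and 1 lower (median 1.82). Ccl2 was at least 11.5-fold higher, a lower bound because its probe was not well above background on the standard-diet array. Of 17 matrix genes 14 were higher and 1 lower (median 2.43), with Sparc at 12.2-fold and Lgals3 at 9.99-fold. Of 17 cell cycle genes 9 were higher and 1 lower (median 1.12), with Mki67 at 10.0-fold.

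All 22 measured Kupffer cell and macrophage markers were at least 2-fold higher on the HFD-IgG array (median 2.82), as were 20 of 22 sinusoidal endothelial markers (median 2.78) and 14 of 20 stellate cell and fibroblast markers (median 2.72). Cd5l of macrophages was 9.27-fold, Gpr182 of endothelial cells 14.9-fold and Colec11 of stellate cells 15.1-fold higher. The 18 hepatocyte markers had a median of 0.02, with 17 within 2-fold and Cps1 2.20-fold lower. Whether the MHC class II, cytokine and matrix genes rose in hepatocytes or came from such other cells was not tested. Lists also share members, such as Ctss in the MHC class II and Kupffer lists and Col3a1 in the matrix and stellate lists. They are therefore not separate evidence. Markers of T and NK cells (median 0.53), of neutrophils and monocytes (0.72), of platelets (1.18) and of cholangiocytes (-0.17) did not stand apart. In the alternatives, however, the cholangiocyte list stood apart below random lists in 7 of 10, the neutrophil and monocyte list above them in 5 of 11, and the T and NK cell list in 2 of 10. The erythroid list stood below random lists (median -0.78), with 3 of 7 at least 2-fold lower and 1 higher, but in 2 of its 10 alternatives it no longer stood apart, with medians of 0.02 with normexp background correction and 0.17 with no filter. Only 4 B and plasma cell markers were measured, too few for a median.

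Among hepatocyte programmes, 11 of 17 male-biased genes were at least 2-fold lower and 0 higher (median -1.34). Cyp4a12a was 10.7-fold lower, with the same caution about similar copies, and Egfr was 4.49-fold lower. The median of the 13 measured female-biased genes was 0.59, with 5 higher and 2 lower, led by Cyp2b13 at no less than 22.0-fold and Cyp2b9 at 14.3-fold. Among those of them above the array's 75th percentile, 5 genes, the median was -0.45, and in 3 of the 11 alternatives the list no longer stood apart. Of 27 genes of fatty acid oxidation and PPAR-alpha targets (the fatty acid oxidation list), 6 were lower and 0 higher (median -0.45), including Ehhadh at 4.39-fold and Acot1 at 3.65-fold. Of 21 xenobiotic genes, 5 were lower and 4 higher (median -0.53, mean -0.0076), with Cyp3a11 4.53-fold lower and Cyp2b9 14.3-fold higher, both of families of similar genes. Of 24 cholesterol genes, 4 were lower and 0 higher (median -0.36), with Sqle, encoding squalene epoxidase, 3.52-fold lower. Of 22 genes of fatty acid and triglyceride synthesis, 4 were lower and 3 higher (median -0.27), with Lpin1 8.48-fold and Acacb 3.26-fold lower. The cholesterol list and the fatty acid and triglyceride list each no longer stood apart in 1 of 11 alternatives. Of 16 pericentral genes 5 were lower and 1 higher (median -0.41), with Oat 4.02-fold lower. Of 20 genes of lipid droplets and fatty acid uptake (the lipid droplet list), 6 were higher and 2 lower (median 0.11), with Fabp4 12.1-fold higher. With probes of at most 50% purines, however, the median was -0.11. In 3 other alternatives, bright genes among them (median -0.02), the list no longer stood apart. Of 10 active-phase circadian genes 3 were at least 2-fold higher and 7 lay between (median 0.52, above random lists), with Dbp at 4.59-fold. Active-phase is only the name of this fixed list, and no phase of its genes was measured. Lists of gluconeogenesis (-0.12), insulin signalling (-0.05), bile acids (-0.11), ER stress (0.07), NRF2 (0.04), oxidative phosphorylation (0.04), opposite-arm circadian genes (-0.21), immediate early genes (0.10) and periportal genes (-0.07) did not stand apart, although the ER stress list did in 5 of 11 alternatives, the opposite-arm circadian list in 3 of 7, and the NRF2 and oxidative phosphorylation lists in 1 of 11 each.

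Vcam1 was 8.71-fold higher on the HFD-IgG array by its brighter probe (chromosome 3, 115813216 to 115813275). Its dimmer probe (115828953 to 115829012) had log2 levels of -5.15 on the standard-diet array, -3.90 on the HFD-IgG array and -5.20 on the anti-VLA-4 array, and was well above background on the HFD-IgG array alone. Itga4 was at least 4.26-fold higher (chromosome 2, 79173193 to 79173252) and Itgb1 was 1.14-fold lower, which is within the scanner error of 0.20 in log2. Of 22 genes of VLA-4, its ligands and leukocyte adhesion, 10 were higher and 0 lower (median 0.62).

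In this comparison 20 of 34 lists stood apart. Over all genes, 4498 of 22002 genes were at least 2-fold higher and 531 lower on the HFD-IgG array than on the standard-diet array, so 89.4% of the differences pointed up. With quantile scaling the counts were 2431 and 2687, or 47.5% up, and among the 8647 genes above the 75th percentile on either array they were 369 and 167. The share of genes called higher was 8.24% where the probe had at most 40% purines (A or G) and 46.9% where it had over 60%.

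**Figure D1:**
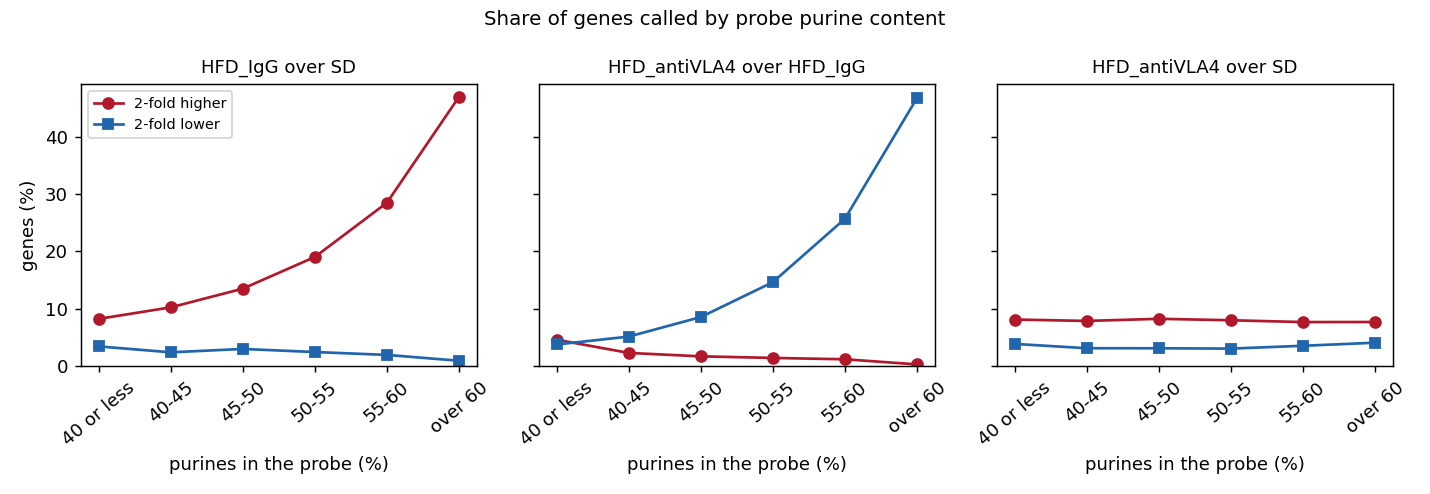
Share of genes at least 2-fold higher (circles) or lower (squares), in percent, by the purine share of the gene's probe, for the 3 comparisons. For HFD-IgG over standard diet the share higher goes from 8.24% to 46.9%, for anti-VLA-4 over HFD-IgG the share lower goes from 3.78% to 46.7%, and for anti-VLA-4 over standard diet the share higher lies between 7.69% and 8.25%.

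The second comparison, anti-VLA-4 over HFD-IgG, asks what blocking VLA-4 altered on the same diet. The medians of the lists of cholesterol, xenobiotic and ER stress genes stood above random lists on the anti-VLA-4 array, and those of endothelial, stellate and Kupffer cell markers stood below them. Of 24 cholesterol genes, 3 were at least 2-fold higher and 0 lower, 22 lay above 0 and the median was 0.54. Sqle was 3.16-fold higher (chromosome 15, 59162688 to 59162747), Msmo1 2.11-fold and Cyp51 1.90-fold. Of 24 genes of the ER stress and amino acid response, 2 were higher and 0 lower (median 0.51). Chac1, which encodes a glutathione-degrading enzyme, was 5.62-fold higher (chromosome 2, 119179990 to 119180049), Hyou1 2.01-fold and Edem1 1.92-fold. Derl3, of the ER-associated degradation pathway, was 4.63-fold higher.

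Of 28 acute phase genes, 4 were higher and 0 lower by 2-fold, 16 lay above 0 and 12 below (median 0.22). Socs3 was 3.94-fold and Mt2 3.28-fold higher, while Saa1 was 1.58-fold and Saa2 1.40-fold lower, these last chosen after their values were seen. Of 21 xenobiotic genes, 2 were higher and 0 lower (median 0.52), Cyp2c37 at 2.34-fold and Cyp2c50 at 2.09-fold, both of a family of similar genes. Medians that also stood above random lists were those of fatty acid and triglyceride synthesis (0.24), male-biased genes (0.24), bile acid genes (0.22), pericentral genes (0.17) and active-phase circadian genes (0.44), with Slco1a1 2.91-fold and Mlxipl 2.10-fold higher. The pericentral list no longer stood apart in 2 of its 11 alternatives and the active-phase circadian list in 1. The fatty acid oxidation list (median 0.08, all 27 genes within 2-fold) stood apart in the main setting and not in 5 of its 11 alternatives. The lipid droplet list stood below random lists (median -0.36), with 3 of 20 genes at least 2-fold lower, among them Cidea at 2.82-fold and Fabp4 at 2.78-fold. Igfbp1 was 4.85-fold higher and Cxcl1 5.41-fold higher.

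Of 22 sinusoidal endothelial markers, 8 were at least 2-fold lower, 0 higher and 0 above 0 (median -0.96), with Gpr182 2.88-fold lower and Lyve1 2.57-fold. Of 20 stellate markers, 7 were lower and 0 higher (median -0.92), with Pdgfrb 19.4-fold lower (log2 difference -4.28, and -1.29 with normexp background correction). Of 23 Kupffer cell markers, 1 was lower (median -0.42), which was Trem2 at 3.25-fold. Hepatocyte (0.05), neutrophil (0.09), T and NK cell (-0.02), B cell (0.24), cholangiocyte (0.01), erythroid (0.03) and platelet (-0.58) medians did not stand apart. The same held for cytokines (0.04), adhesion genes (0.13), interferon-stimulated genes (-0.10), MHC class II (-0.18), matrix (-0.43), cell cycle (0.14), gluconeogenesis (0.01), insulin signalling (0.18), female-biased (0.04), NRF2 (-0.08), oxidative phosphorylation (-0.15), opposite-arm circadian (0.02), immediate early (0.16) and periportal genes (-0.13). In the alternatives, however, the matrix list stood apart below random lists in 7 of 10 and the insulin signalling list above them in 5 of 11. The cytokine list stood apart in 3 of its alternatives, the T and NK cell, female-biased and immediate early lists in 2 each, and the hepatocyte, neutrophil and periportal lists in 1 each. Vcam1 was 1.82-fold lower by its brighter probe, Itga4 1.47-fold lower and Itgb1 1.14-fold higher.

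In this comparison 14 of 35 lists stood apart. Over all genes, 429 of 22589 were at least 2-fold higher and 3721 lower on the anti-VLA-4 array, so 10.3% of the differences pointed up. With quantile scaling the counts were 2462 and 2067, or 54.4% up, with normexp background correction 68 and 150, or 31.2% up, and among the 8562 genes above the 75th percentile they were 69 and 111. The anti-VLA-4 array lay on another slide than the other arrays, so slide and antibody cannot be told apart.

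The third comparison, anti-VLA-4 over standard diet, sets no HFD-IgG value in its differences. The HFD-IgG array still had a part in choosing the probe of genes with several and in leaving out flagged probes. It also entered the mean signal on which random lists were matched. Diet, injection, antibody and slide all differ together here and cannot be told apart. The medians of the lists of Kupffer, endothelial and stellate markers, MHC class II, cytokines, interferon-stimulated and acute phase genes stood above random lists, and those of male-biased and fatty acid oxidation genes stood below them. Of 23 Kupffer cell markers 22 were at least 2-fold higher (median 2.42), with Mpeg1 at 7.98-fold and Ctss at 6.91-fold. Of 22 endothelial markers 20 were higher (median 1.78), with Fcgr2b at 5.08-fold, and of 18 stellate markers 14 were higher (median 1.88), with Colec11 at 7.92-fold. Of 13 neutrophil and monocyte markers 6 were higher (median 0.92), with S100a8 at 11.4-fold and S100a9 at 8.16-fold, and of 6 B and plasma cell markers 4 (median 1.14), a list that no longer stood apart in 1 of its 7 alternatives. Of 6 erythroid markers 3 were lower and 0 higher (median -0.92), with a median of 0.11 under normexp background correction that did not stand apart. Medians of T and NK cell (0.35), cholangiocyte (-0.10), platelet (0.25) and hepatocyte (-0.13) markers did not stand apart, although the T and NK cell list did in 1 of 10 alternatives.

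Of 28 acute phase genes 10 were higher and 0 lower (median 0.60). Hamp2, a hepcidin gene, was 42.8-fold higher (chromosome 7, 31707520 to 31707579), Saa1 12.3-fold and Lcn2 13.5-fold. Of 11 MHC class II genes 9 were higher (median 2.55), of 31 interferon-stimulated genes 19 (median 1.12), of 26 cytokine genes 19 (median 1.53), of 19 matrix genes 13 with 1 lower (median 1.65), of 18 cell cycle genes 9 with 1 lower (median 1.105) and of 23 adhesion genes 10 (median 0.80). Among bright genes the adhesion list had a median of 0.26 and did not stand apart. Cxcl1 was 19.1-fold, Oas1a 6.27-fold and Mki67 12.1-fold higher. The lists of ER stress (median 0.61), active-phase circadian (0.80), cholesterol (0.23) and bile acid genes (0.16) also stood above random lists, with Chac1 at 8.71-fold and Dbp at 6.46-fold. The cholesterol list no longer stood apart in 1 of its 11 alternatives and the bile acid list in 2, with normexp (median -0.20) and with at most 50% purines (0.10). The immediate early list (median 0.31) stood above random lists too, but not in 4 of its 11 alternatives.

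Of 17 male-biased genes 8 were lower and 0 higher (median -0.99), with Cyp4a12a at 9.77-fold. Of 27 fatty acid oxidation genes 5 were lower and 0 higher (median -0.46), with Ehhadh at 4.99-fold and Acot1 at 4.74-fold. Of 16 pericentral genes 4 were lower and 1 higher (median -0.37), with Oat 3.52-fold lower, and the list no longer stood apart in 2 of its 11 alternatives. Medians of fatty acid and triglyceride synthesis (-0.24), lipid droplet (-0.12), gluconeogenesis (-0.08), insulin signalling (0.09), xenobiotic (0.08), female-biased (0.13), NRF2 (-0.06), oxidative phosphorylation (-0.14), opposite-arm circadian (-0.24) and periportal genes (-0.09) did not stand apart, although the xenobiotic list did in 5 of 11 alternatives and the female-biased list in 2 of 11. Cyp2b9 was 27.2-fold higher. Vcam1 was 4.78-fold higher by its brighter probe, while its dimmer probe, not well above background on either array, read -5.15 on the standard-diet and -5.20 on the anti-VLA-4 array. Itga4 was at least 2.90-fold higher and Itgb1 1.01-fold lower.

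In this comparison 21 of 35 lists stood apart. Over all genes, 1623 of 20334 genes were at least 2-fold higher and 690 lower, so 70.2% pointed up. With quantile scaling the counts were 1156 and 861, or 57.3% up, with normexp background correction 6108 and 423, or 93.5% up, and among the 8575 genes above the 75th percentile they were 286 and 133.

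**Figure D2:**
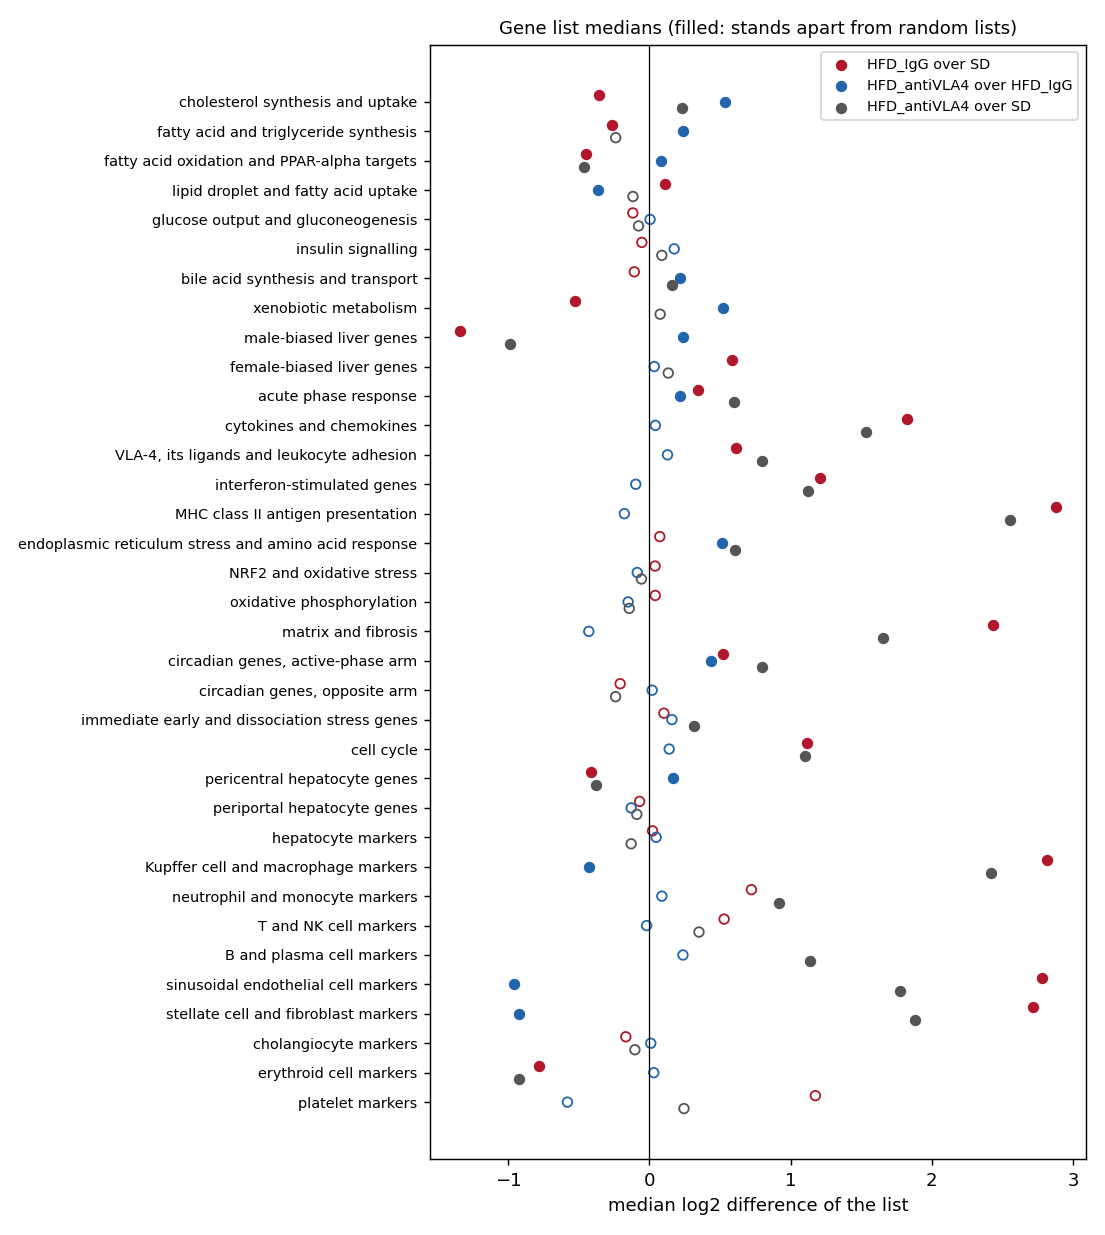
Median log2 difference of each gene list or marker list in the 3 comparisons, with filled points for lists that stood apart from random lists and open points for the others. A list with fewer than 5 measured members has no point. Kupffer cell markers lie at 2.82 and 2.42 on the high-fat diet arrays over standard diet, and male-biased genes at -1.34 and -0.99.

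Whether genes altered on the HFD-IgG array lay nearer to standard diet on the anti-VLA-4 array was examined over the 17036 genes well above background on all 3 arrays. Of 1796 genes at least 2-fold different between HFD-IgG and standard diet, 1530 lay nearer to standard diet on the anti-VLA-4 array (85.2%, exact binomial interval from 83.5% to 86.8%, which covers counting of genes and not arrays). Most of them, 1441, were higher on the HFD-IgG array, and 88.1% of these lay nearer. Of the 355 lower genes, 73.2% did. The simulated shares below were not split in this way. The slope of the difference anti-VLA-4 minus HFD-IgG on the difference HFD-IgG minus standard diet was -0.41 (r = -0.58 across genes, which are not independent replicates; covariance -0.23). The HFD-IgG array enters both differences. A simulation with equal error on each array and no difference between them gave a slope of -0.50, a covariance of -0.28 and a share of 84.2%. A simulation with error on the HFD-IgG array alone and no antibody effect gave -0.43, -0.28 and 87.1%. With the scanner's error and no antibody effect, the values were -0.04, -0.03 and 57.4%. A simulation with error on the HFD-IgG array alone around the mean of the other arrays gave -0.55, -0.23 and 80.9%. The observed share of 85.2% lay between those of the simulations with error on the HFD-IgG array alone, and the observed slope of -0.41 was smaller in size than in both. The equal error, 0.53 in log2, was set from the observed spread of HFD-IgG minus standard diet, so that whole difference counted as error. Error on the HFD-IgG array alone was likewise sized from its observed deviation. Both show what such error would give, not that it was present. Equal error made 3083 genes at least 2-fold different and error on the HFD-IgG array alone 3082 or 2027, against 1796 observed.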

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

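The tests of purine content over all genes and receptor probes and of cell type markers were chosen after their results were seen. Those of scaling, of the mirrored share and of purine content in bright genes were written before their own results. The mirrored share and the limits on purines and brightness were themselves chosen after other results had been seen, so these tests were not planned from the start. Intervals in this section are bootstraps over genes of the same arrays. Genes are not independent replicates, so the intervals do not cover the spread between arrays, mice or preparations.

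Signal appeared in control spots outside the main measurement. Spots of the adenoviral E1A control were well above background for 64.7% on the HFD-IgG array, against 10.0% on the standard-diet array and 12.2% on the anti-VLA-4 array. These spots repeat 10 probes, of which some had 25 to 32 of 32 spots so on the HFD-IgG array and others 0 to 3, so that spots are not independent. Spike-in control spots were so for 16.8% on the HFD-IgG array, against 3.20% and 9.20%. Among 1509 probes of olfactory, vomeronasal and taste receptors, 32.5% were well above background on the HFD-IgG array, 14.4% on the standard-diet array and 18.1% on the anti-VLA-4 array.

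The excess of higher genes on the HFD-IgG array over standard diet, and of lower genes in anti-VLA-4 over HFD-IgG, followed the purine content of the probe. Genes with over 60% purines were called higher 5.69 times as often as genes with at most 40%, against 0.95 times for anti-VLA-4 over standard diet, and over the receptor probes Spearman's rho between purine share and the difference was 0.65, against -0.02. Nonspecific signal on purine-rich probes of the HFD-IgG array is a candidate explanation for much of the excess. The scaling stays open: with quantile scaling, which forces equal distributions, the ratio of higher to lower genes was 0.67 times that of anti-VLA-4 over standard diet, and with cyclic loess 2.30 times. A true effect of diet on dim genes was not tested apart from this.

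Kupffer, endothelial and stellate markers were higher on both high-fat diet arrays than on the standard-diet array. Purine-rich signal of the HFD-IgG array is argued against for the rise on the anti-VLA-4 array. There the 37 such markers with at most 50% purines had a median of 1.955 over standard diet (bootstrap interval 1.72 to 2.26). The larger medians of these markers on the HFD-IgG array were not tested in this way. A lower hepatocyte share raising all other types alike stays open: these markers exceeded those of cholangiocytes and T and NK cells by 1.93 (1.40 to 2.18), but among markers well above background and not above the 75th percentile on the standard-diet array they exceeded 24 of other types by 1.90 (0.11 to 2.27) and 11 of leukocytes by 0.97 (-1.03 to 1.79). More sinusoidal cells left in the high-fat diet preparations, the bright markers Cd5l and Clec4g reaching log2 levels of 3.77 and 3.70 on the anti-VLA-4 array, cannot be told apart from more such cells or transcripts in the liver: the 3 medians differed by 0.64 (0.20 to 0.99), and each group had 1 array. An effect of the diet stays open and untested.

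Genes altered on the HFD-IgG array lay nearer to standard diet on the anti-VLA-4 array. The share exceeded its mirror, in which the HFD-IgG value is the nearer one for genes different between anti-VLA-4 and standard diet, by 33.8 percentage points (30.1 to 38.1), a gap that had been set in advance to exclude error of the HFD-IgG array. That bound was wrong, as error on 1 array does not enter the share and its mirror alike: error on the HFD-IgG array alone with no antibody effect, simulated after the result was seen, gave a gap of 36.9, whereas such error around the mean of the other arrays gave -9.30 and equal error on all arrays 0.13. Among bright genes with at most 50% purines the gap was 28.9 (18.9 to 39.4), so signal on probes of over 50% purines is argued against as the whole cause. That limit does not remove the purine trend. Over all genes the share called higher on the HFD-IgG array over standard diet was 8.24% with at most 40% purines and 13.5% with 45% to 50%. Purine-related signal below the limit, other error of the HFD-IgG array, the slide and an effect of the antibody cannot be told apart with 1 array per group.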

How the results depend on the processing

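Settings with purines, bright genes and the mirrored share were chosen after seeing the data. Counts below are genes higher and lower, for HFD-IgG over standard diet, anti-VLA-4 over HFD-IgG and anti-VLA-4 over standard diet in this order, and the cause of a change was not tested unless stated. Dim signal limits the counts: 2964 of the 4498 higher genes of the first comparison and 2486 of the 3721 lower genes of the second are bounds against an array where the probe was not well above background.

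With quantile scaling the counts were 2431 and 2687, 2462 and 2067, and 1156 and 861, the slope was -0.51 and the share nearer to standard diet 90.9%. With cyclic loess they were 3535 and 899, 716 and 3117, and 1450 and 849. With normexp background correction, which moved the median of all genes to 0.46, -0.14 and 0.27, they were 8857 and 862, 68 and 150, and 6108 and 423, with slope -0.24 and share 96.2%. With genes well above background on all 3 arrays they were 1441 and 355, 262 and 735, and 998 and 354, and with no filter 7461 and 1100, 1191 and 6351, and 3417 and 1829 (slope -0.72, share 87.7%). The deposited value table gave 1451 and 355, 262 and 741, and 1006 and 354. By construction the thresholds moved the counts, to 6149 and 1713, 1607 and 5269, and 3323 and 1915 at 1.5-fold, and to 2865 and 165, 92 and 2183, and 743 and 261 at 3-fold. With probes of at most 50% purines, fewer in number, the counts were 1280 and 350, 332 and 749, and 967 and 400 (slope -0.33, share 82.5%). Among bright genes they were 369 and 167, 69 and 111, and 286 and 133 (slope -0.29, share 77.2%), and 13 lists stood apart in the third comparison. Lists left with fewer than 5 bright members there, such as MHC class II and stellate markers with 4 each, were not scored. With the mean over probes the slope was -0.45 and the share 87.5%. The mirrored share was 51.4%.

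Of 1093 list medians over all alternatives, 1005 kept their side of the threshold, 56 newly stood apart, 30 no longer did and 2 reversed relative to random lists: in HFD-IgG over standard diet, lipid droplet genes at -0.11 with at most 50% purines and female-biased genes at -0.45 among bright genes. Of 2546 values of named genes, 2132 moved by less than the scanner error, 411 moved further, 255 of them with normexp, and 3 reversed. Part of these totals could hardly change. The 247 values of genes well above background on all 3 arrays are the main values again. The median of bright probes shifts each array by a constant, and all its 314 gene values and 104 list medians stayed the same. Both totals therefore overstate how stable the results are. With normexp, Cspg5 and Sp5 were at 0.40 and 0.52 in anti-VLA-4 over standard diet. With the mean over probes Cdk15 was at -0.011 in anti-VLA-4 over HFD-IgG. No replicate could be left out, as each group has 1 array.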

Other observations

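Some genes departed on the HFD-IgG array. Syt10 was 32.9-fold lower there than on the standard-diet array and 12.9-fold higher on the anti-VLA-4 array than there (chromosome 15, 89612967 to 89613026), and Neat1, a nuclear noncoding RNA, was 5.69-fold higher on the anti-VLA-4 array. Several of the genes highest on the HFD-IgG array over standard diet were dim on both other arrays: Hoxc5 was 31.5-fold and Creg2 30.6-fold higher, and Hoxc5 was 27.2-fold lower on the anti-VLA-4 array.

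Other genes moved alike on both high-fat diet arrays. Serpina4-ps1 was 14.1-fold lower on the HFD-IgG array and 15.4-fold lower on the anti-VLA-4 array than on the standard-diet array, and Zbtb16 11.4-fold and 9.05-fold lower. Asns, which encodes asparagine synthetase, was 7.17-fold and 10.1-fold lower, while the median of the ER stress list that holds it was 0.07 and 0.61.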
